A study of Mus musculus with 2 samples.

How the data were processed

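H3K4me1, histone H3 monomethylated at lysine 4, was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in limb tissue of mouse embryos at embryonic day 14.5. Per the labels, there were 2 biological replicates of 1 group. Limbs of 24 embryos were pooled for replicate 1 and limbs of 34 embryos for replicate 2, with males and females pooled in both, and the animals were healthy and of the strain B6NTac;B6NCrl/Lap. No second tissue, stage or treatment was part of the series, so no comparison between conditions was possible, and no p-value between groups is given.

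The authors deposited 4 lists of peaks on the mm10 assembly: 1 for each replicate, 1 called on both replicates pooled, and 1 of replicated peaks. Per the deposited file descriptions, alignments were filtered before the peaks were called, the list of replicate 1 was made with 2 control files and that of replicate 2 with 1 of these, the pooled list was made from both replicates and both controls, and the replicated list was made from the pooled list and both replicate lists. The aligner and the peak caller are not given in the sources used here. In each deposited list the authors give a signal value per peak, used here as the peak's enrichment value, and −log10 p and −log10 q values. The rule that made a pooled peak a replicated one is not stated. These values are the authors' own and were used to describe, rank or filter peaks within a list, and for peaks found in both replicate lists to compare them. The lists hold no read counts, so the depth of each library is unknown, and no interval that needs a depth is given.

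Peak positions were set against the GRCm38.p6 reference sequence and the GENCODE vM21 annotation, which share the mm10 chromosomes. No peak in any of the 4 lists ran past the end of a chromosome. Peaks on chromosomes 1 to 19, X and Y were used, which left out 2 peaks of replicate 1 on an unplaced sequence of chromosome X. Protein-coding genes were taken once per symbol, which gave 21911 genes, and the transcription start site (TSS) of a gene was its annotated 5′ end. A promoter was called CpG-rich where the observed-to-expected CpG ratio within 500 bp of the TSS was above 0.6.

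A peak was counted as shared when it overlapped a peak of the other list by at least 50% of the shorter of the 2. Shares were set beside 100 random placements of the peaks on their own chromosomes outside assembly gaps, which do not model where reads can be aligned. Peaks were placed by their summit within 1 kb of a TSS, 1 to 10 kb from one, or further away in an exon, an intron or between genes. Around each gene, the length covered by replicated peaks within 50 kb of the TSS was summed. For 24 gene lists fixed before the data were examined, the median over members was given as a percentile among 10000 random lists of the same size, matched on gene length and on the number of neighbouring genes within 50 kb. For 26 intervals around developmental genes, also fixed before the data were examined, the covered share was given as a percentile among 1000 random intervals of the same length, not matched on gene density. The intervals on either side of the HoxA cluster are named by their bounding genes, because the sides first given to them were exchanged. Percentiles describe these libraries and are not p-values. Windows of neighbouring genes overlap, so 1 peak can count for several genes.

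The genes named were set by a rule before the data were examined. It took the 4 members of each list with the most covered length and the member with the least, all members of the 4 Hox clusters, the 20 genes with the most covered length, the 10 strongest and the 10 widest peaks with the gene of the nearest TSS, the strongest peak of each interval, and the introns of Lmbr1 that hold peaks. Members that repeat a neighbour, and part of the strongest peaks of intervals, are left out of the text. Other names were chosen after their values were seen and are given as such. Of the symbols in the lists, 1 had no match in the annotation (Ahsp). Lmbr1 introns were numbered on the 17-exon principal transcript.

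Values are given for the replicated list, with the mean ± SD over the lists of the 2 replicates where a spread is given. The 2 lists differ in length, so this SD takes in that difference too, and no SD was computed for lists of equal length. The alternatives were another minimum overlap, stricter thresholds, equal numbers of peaks, each replicate left out, pooled in place of replicated peaks, other windows and measures, and random lists without matching. Added after the data were examined were pooled peaks with the 50% overlap in both replicates' own lists, lists without genes on chromosome X, lists with 1 member of each group of overlapping windows, the 50000 strongest peaks of each replicate, and a replicated list rebuilt with an overlap of 1 bp.

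The functions were tested on simulated data. For the replicate overlap, 40% of 48885 simulated peaks were planted in a second list, and 40% were found shared. That second list held only planted peaks of equal width, so this checks the counting and does not model the deposited lists. Random lists of that size shared 1.38% of peaks by 1 bp, against 1.51% calculated from the genome size. For gene list coverage, lists of 25 genes were drawn from 21911 genes, and 2.5% of 200 unchanged lists and 100% of 50 lists with a planted rise reached the 95th percentile. The simulated values were drawn separately for each gene, so windows shared by neighbours were not modelled. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.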

Results

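H3K4me1 marks enhancers, active or poised, and the flanks of active promoters. Its peaks were mapped in limb tissue of mouse embryos at embryonic day 14.5 in 2 biological replicates, pools of 24 and 34 embryos. Replicate 1 had 173109 peaks that covered 71.1 Mb, and replicate 2 had 109430 peaks that covered 38.3 Mb. The pooled data gave 151844 peaks, of which the authors kept 99452 as replicated. These replicated peaks covered 62.996 Mb, or 2.38% of the genome, with a median width of 478 bp and a median enrichment value of 3.34. Read depth is unknown for both libraries.

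The first question was which limb genes lie in H3K4me1-rich surroundings. Transcription factors of limb patterning had a median of 9.85 kb of replicated peaks within 50 kb of the TSS, against 2.16 kb for all 21911 protein-coding genes. The median for limb signalling genes was 7.12 kb, for cartilage genes 6.43 kb, and for tendon and joint genes 4.74 kb. In the lists of the replicates, the patterning factors had 7.34 ± 2.70 kb, the signalling genes 6.22 ± 2.55 kb, the cartilage genes 4.58 ± 2.47 kb and the tendon and joint genes 4.58 ± 2.10 kb (mean ± SD, n = 2). These 4 lists lay between the 99.9th and the 100th percentile of matched random lists, and at or above the 98.4th percentile under every alternative run. Osteoblast genes, with a median of 3.53 kb, lay at the 93.1st percentile and skeletal muscle genes, with 2.498 kb, at the 86.3rd. The osteoblast list ranged from the 87.6th to the 99.7th percentile over the alternatives and the muscle list from the 67.9th to the 99.2nd. With the peaks of replicate 1 alone they lay at the 99.7th and the 95.4th percentile, and with those of replicate 2 alone at the 88.0th and the 93.8th.

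**Figure D1:**
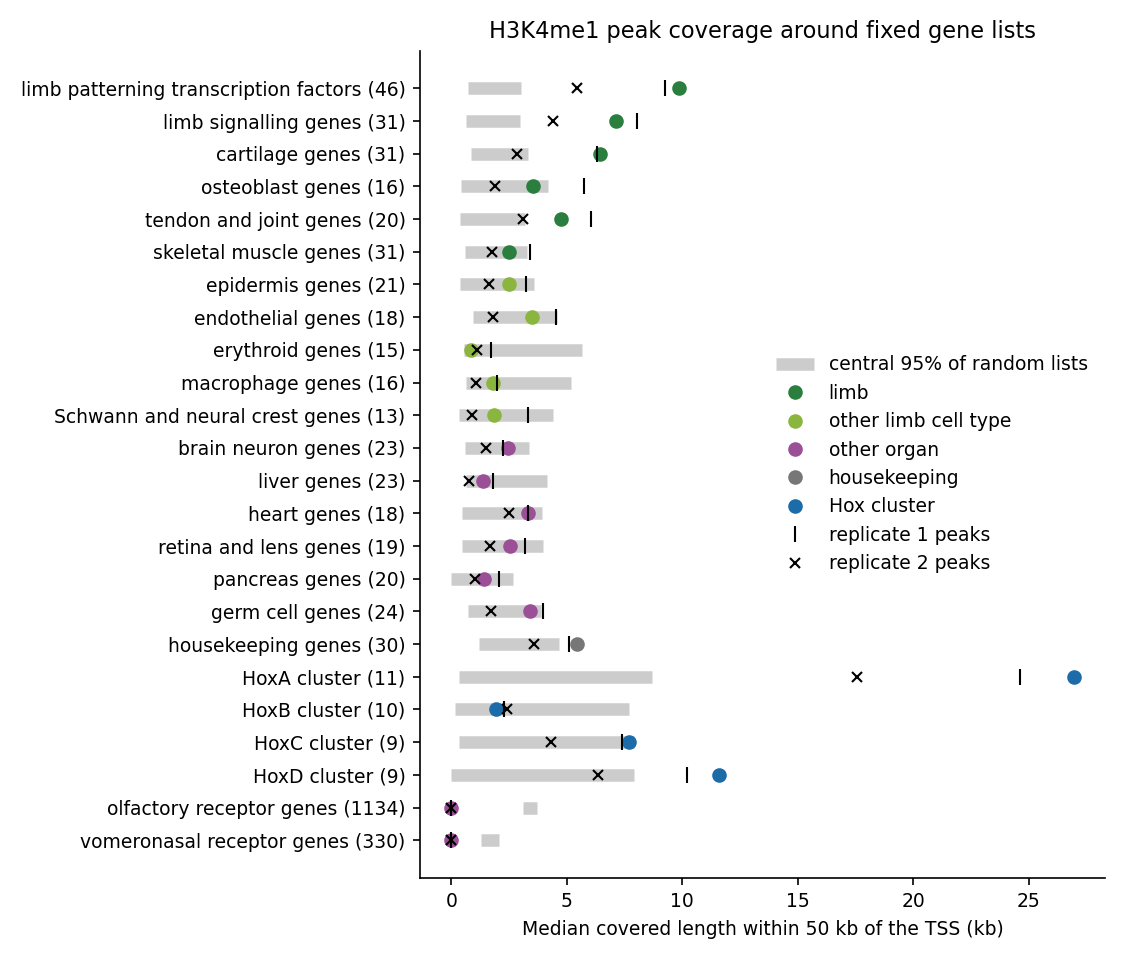
Median covered length within 50 kb of the TSS (x axis, kb) for the 24 fixed gene lists (y axis, number of genes in brackets). Dots give replicated peaks, coloured by kind of list, ticks and crosses give the peaks of each replicate, and grey bars give the central 95% of 10000 matched random lists for replicated peaks. The limb patterning factors, at 9.85 kb, and the HoxA cluster, at 26.95 kb, lie far to the right of their bars, and the receptor gene lists lie at 0.

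Of the 46 patterning factors, 42 were above the median of all genes and none was without a peak. The homeobox gene Prrx2 (chromosome 2, 30834972 to 30881251) had the most covered length, 28.9 kb in 30 peaks, with 24.9 ± 1.77 kb in the replicates (SD, n = 2). Hoxa9 followed with 27.7 kb, then the zinc finger gene Bcl11a with 26.4 kb and Hoxa10 with 25.1 kb. Tfap2b had the least, 0.198 kb in 1 peak. Several members are neighbours in the Hox clusters, and with 1 member of each group of overlapping windows the median over 36 genes was 7.78 kb, still at the 100th percentile. Of the 31 signalling genes, 23 were above the median of all genes. Pth1r, the receptor for parathyroid hormone-related protein in growth plate cartilage, had 21.3 kb (18.1 ± 4.95 kb in the replicates). Ptch1, the Hedgehog receptor, had 21.3 kb as well (17.3 ± 1.76 kb), Fgfr1 had 20.1 kb (16.2 ± 2.96 kb) and Bmp7 had 19.5 kb (16.2 ± 2.92 kb). Fgf10, a growth factor needed for limb bud outgrowth, had no replicated peak within 50 kb of its TSS, although the lists of the replicates themselves covered 0.437 ± 0.0601 kb there.

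Among the 31 cartilage genes, 24 were above the median of all genes. The matrix genes Matn4 and Comp had 19.6 and 16.7 kb, the transcription factor gene Runx3 had 17.4 kb and the fibrillar collagen gene Col27a1 had 14.6 kb. Acan, which encodes the main proteoglycan of cartilage, had the least with 0.814 kb in 3 peaks. Among the 16 osteoblast genes, Col1a1, the gene of the main bone collagen, had 15.2 kb (12.7 ± 2.22 kb in the replicates), Ifitm5 had 13.5 kb, Sparc had 11.7 kb and Sp7, which encodes the transcription factor osterix, had 10.9 kb. Among the 20 tendon and joint genes, 17 were above the median of all genes. Fmod had 18.4 kb, Tgfb2 17.1 kb, Htra1 17.0 kb and Scx, a transcription factor gene of tendon progenitors, 16.5 kb. The members with the least, Phex of the osteoblast list and Tnmd of the tendon list, had no peak, and both lie on chromosome X, which had few peaks in all. Of the 31 skeletal muscle genes, 17 were above the median of all genes. The fast troponin genes Tnnt3 and Tnni2, which are neighbours on chromosome 7, had 45.3 and 24.3 kb. The fusion factor gene Mymk had 19.1 kb and the slow troponin gene Tnni1 had 16.9 kb, whereas Myh8, a myosin gene of perinatal muscle, had no replicated peak.

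No list of the other cell types that a dissected limb holds reached the 95th percentile. Epidermis genes (median 2.51 kb) lay at the 83.0th percentile, endothelial genes (3.51 kb) at the 86.5th, macrophage genes (1.82 kb) at the 29.7th, Schwann cell and neural crest genes (1.86 kb) at the 49.6th and erythroid genes (0.869 kb) at the 5.27th. Without the 2 erythroid genes on chromosome X, the erythroid median was 3.03 kb, at the 55.0th percentile. These percentiles moved widely over the alternatives: from 65.7 to 97.6 for epidermis, 51.1 to 96.1 for endothelial, 1.34 to 50.8 for macrophage, 37.8 to 87.9 for Schwann cell and neural crest and 5.09 to 60.7 for erythroid genes. With the peaks of replicate 1 alone and of replicate 2 alone, endothelial genes lay at 95.3 and 74.2, Schwann cell and neural crest genes at 83.4 and 37.8, and erythroid genes at 13.6 and 23.1. The lowest endothelial value, 51.1, was that with 1 member of each group of overlapping windows. Some single members were high, and others were not. Against matched genes, the 4 members with the most covered length lay at the 86.3rd to 98.4th percentile in the epidermis list. They lay at the 94.6th to 99.8th in the endothelial list and the 76.1st to 96.1st in the macrophage list. In the Schwann cell and neural crest list they lay at the 70.8th to 99.8th, and in the erythroid list at the 50.2nd to 99.8th. Grhl3, an epidermal transcription factor gene, had 16.6 kb, and Krt8 and Krt18, keratin genes of simple epithelium and periderm, had 10.98 and 9.10 kb. Irf6 had 7.46 kb. Krt5 of the basal epidermis had no replicated peak. The endothelial genes Fli1, Eng and Erg had 26.98, 17.4 and 14.3 kb. Lyl1 had 48.7 kb, but lies within the span of Nfix. The neurotrophin receptor gene Ngfr had 30.5 kb, and the neural crest factor genes Sox10 and Mitf had 5.38 and 4.03 kb beside Mpz with 5.28 kb. The erythroid factor gene Nfe2 had 23.5 kb, Klf1 5.46 kb, Tfrc 5.35 kb, Epor 4.27 kb and the globin gene Hbb-bt none. The macrophage genes Fcer1g, Laptm5, Cd68 and Csf1r had 13.6, 12.2, 9.75 and 7.58 kb. Emcn, Mrc1 and Plp1 had no replicated peak.

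Of the 8 lists of other organs, 0 reached the 95th percentile. Heart genes (3.34 kb) lay at the 93.3rd percentile, germ cell genes (3.405 kb) at the 93.2nd, brain neuron genes (2.46 kb) at the 85.5th, retina and lens genes (2.55 kb) at the 73.9th, pancreas genes (1.44 kb) at the 71.9th and liver genes (1.38 kb) at the 16.6th. Of 1134 olfactory receptor genes, 1020 had no replicated peak within 50 kb, and of 330 vomeronasal receptor genes 310 had none, and both lists lay at percentile 0. Olfr70 had the most of these, 7.24 kb, and Vmn1r188 had 3.63 kb. Windows take in neighbouring genes in these lists as in the limb lists: Myl3 of the heart list had the same 21.3 kb as its neighbour Pth1r, Spo11 (17.6 kb) lies beside Bmp7, and Gnat1 of the retina (30.6 kb) lies beside Sema3f. Cpa1 of the pancreas had 35.3 kb, followed by Cel with 15.1 kb, Ctrb1 with 11.9 kb and Cela2a with 5.79 kb. Camk2a of the brain had 24.5 kb, followed by Emx1 with 6.64 kb, Lhx6 with 5.85 kb and Eomes with 5.501 kb. Apoa2 of the liver had 12.8 kb, Foxa3 6.80 kb, Pck1 6.30 kb and Tat 3.39 kb. In the heart list Myl7 had 10.08 kb, Hand1 8.07 kb, Tnni3 6.79 kb and Actn2, with the least, 0.9 kb. In the retina list Opn1sw had 10.065 kb, Rho 7.0 kb and Gnat2 5.40 kb, and in the germ cell list Prm1 had 14.7 kb, Prm2 11.3 kb and Piwil2 10.9 kb. Gabra1, Ttr, Rpe65, Prss1 and Sycp1 had no replicated peak. With the peaks of replicate 2 alone the heart list reached the 98.3rd percentile, and with those of replicate 1 alone the germ cell list reached the 96.2nd. Over all alternatives the heart list ranged from 51.7 to 98.6, the germ cell list from 8.21 to 96.2, the brain list from 48.9 to 94.2, the retina list from 49.6 to 86.5, the pancreas list from 18.9 to 91.2 and the liver list from 5.43 to 59.96. Within 10 kb of the TSS the heart list lay at 51.7 and the germ cell list at 11.3, and over gene bodies with 5 kb on each side at 70.1 and 8.21. Housekeeping genes had a median of 5.43 kb, at the 99.4th percentile (94.99 by number of peaks), with 20.99 kb at Rplp0, 13.1 kb at Polr2a, 12.8 kb at Tubb5, 11.7 kb at Hsp90ab1 and none at Pgk1 on chromosome X.

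The 4 Hox clusters, whose 5′ members pattern the limb in the HoxA and HoxD clusters, differed. In HoxA, all 11 genes had between 18.2 kb (Hoxa1) and 31.1 kb (Hoxa5), with 19.1 kb at Hoxa13, 24.4 kb at Hoxa11 and 30.8 kb at Hoxa6. The cluster median of 26.95 kb was 21.1 ± 4.996 kb in the replicates (SD, n = 2). In HoxD, Hoxd10 had 12.6 kb, Hoxd13 11.1 kb and Hoxd1 5.26 kb, with a median of 11.6 kb (8.27 ± 2.73 kb in the replicates). In HoxC, Hoxc6 had 8.88 kb, Hoxc8 8.62 kb, Hoxc4 8.22 kb, Hoxc11 5.21 kb, Hoxc12 2.83 kb and Hoxc13 1.65 kb, with a median of 7.69 kb (5.84 ± 2.17 kb). In HoxB, values ran from 3.05 kb at Hoxb1, the 1 member above the median of all genes, to 0.282 kb at Hoxb13, with a median of 1.95 kb (2.36 ± 0.105 kb), at the 21.7th percentile (55.5 with the peaks of replicate 2 alone). The gap between HoxA and HoxB was larger than the SD between replicates. Members of a cluster share most of their windows whereas random lists hold scattered genes, so a cluster percentile describes about 1 locus, and no alternative with 1 member per group was run for the clusters. Taken singly against matched genes, the members lay at the 98.6th to 99.7th percentile in HoxA, the 87.0th to 94.9th in HoxD, the 47.0th to 89.3rd in HoxC and the 8.85th to 69.2nd in HoxB. As a list, HoxA lay at the 100th percentile of matched random lists in every alternative run. HoxD lay at the 99.96th and HoxC at the 96.7th, but HoxD ranged from the 82.1st to the 100th over the alternatives and HoxC from the 34.1st to the 99.8th. With a window of 10 kb they lay at 89.4 and 85.9, with the stronger 50% of peaks at 94.2 and 53.7, and HoxC with the peaks of replicate 2 alone at 90.9.

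Intervals known to hold limb enhancers were compared with random intervals of the same length. Of 18 limb intervals, 4 reached the 95th percentile, and of 8 intervals of other organs 0 did. The median covered share was 5.65% of the limb intervals and 0.163% of the others. Prrx1 (chromosome 1, 163245119 to 163313710) was covered to 20.6%, with 16.3 ± 7.17% in the replicates, and held a peak of 2366 bp from 163281380 to 163283745 with an enrichment value of 6.24. The interval from Hoxa13 to Evx1, beside the HoxA cluster (chromosome 6, 52260881 to 52313497), was covered to 13.1% (11.4 ± 1.35%). The span from Gdf5, a joint gene, to Uqcc1 was covered to 11.3% (8.499 ± 2.56%), and the gene desert downstream of Sox9, the master gene of cartilage, to 10.3% (8.30 ± 4.04%). That desert held a peak with a value of 6.57 at chromosome 11, 113015275 to 113016545. Pitx1 to Macroh2a1 (8.84%), Fbxw4 to Fgf8 (8.56%) and Tbx4 to Tbx2 (7.60%) lay between the 91.2nd and the 94.0th percentile. The deserts beside HoxD were covered to 6.77% on the centromeric side, where digit enhancers lie, and to 5.42% on the telomeric side, with strongest peaks of value 5.30 and 5.37. With the stronger 50% of peaks, 2 limb intervals reached the 95th percentile, and with the peaks of replicate 1 alone the Gdf5 span lay at the 94.4th and Pitx1 to Macroh2a1 at the 95.4th.

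Of the other limb intervals, Runx2 was covered to 5.88%, Tbx5 to Tbx3 to 5.24%, Skap2 to Hoxa1, on the other side of HoxA, to 3.48%, the upstream desert of Sox9 to 2.84%, Fmn1 to 2.23%, Ihh to Nhej1 to 1.94%, the Bmp2 desert to 1.64% and Epha4 to Pax3 to 1.498%. The span from Shh to Lmbr1, which holds the distant limb enhancer of Shh, was covered to 0.447%, at the 32.2nd percentile, with 11 peaks, the strongest with a value of 4.60 at 28463987 to 28464467 on chromosome 5. Lmbr1 had 2 peaks in intron 5, at chromosome 5, 29314352 to 29314563 with a value of 3.49 and 29314742 to 29315134 with a value of 3.98, and 1 in intron 1 at 29377388 to 29377759 with a value of 4.11. Among the intervals of other organs, Rho to Ift122 was covered to 5.95% and Pdx1 to Cdx2 to 2.83%. The neuronal gene Grin2b was covered to 0.898%, the cardiac gene Ryr2 to 0.248%, Csmd3 to 0.0775% and the brain interval from Foxg1 to Prkd1 to 0.0533%. Alb to Afp, the albumin genes of liver, and Pou3f2 to Fbxl4 had no replicated peak.

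**Figure D2:**
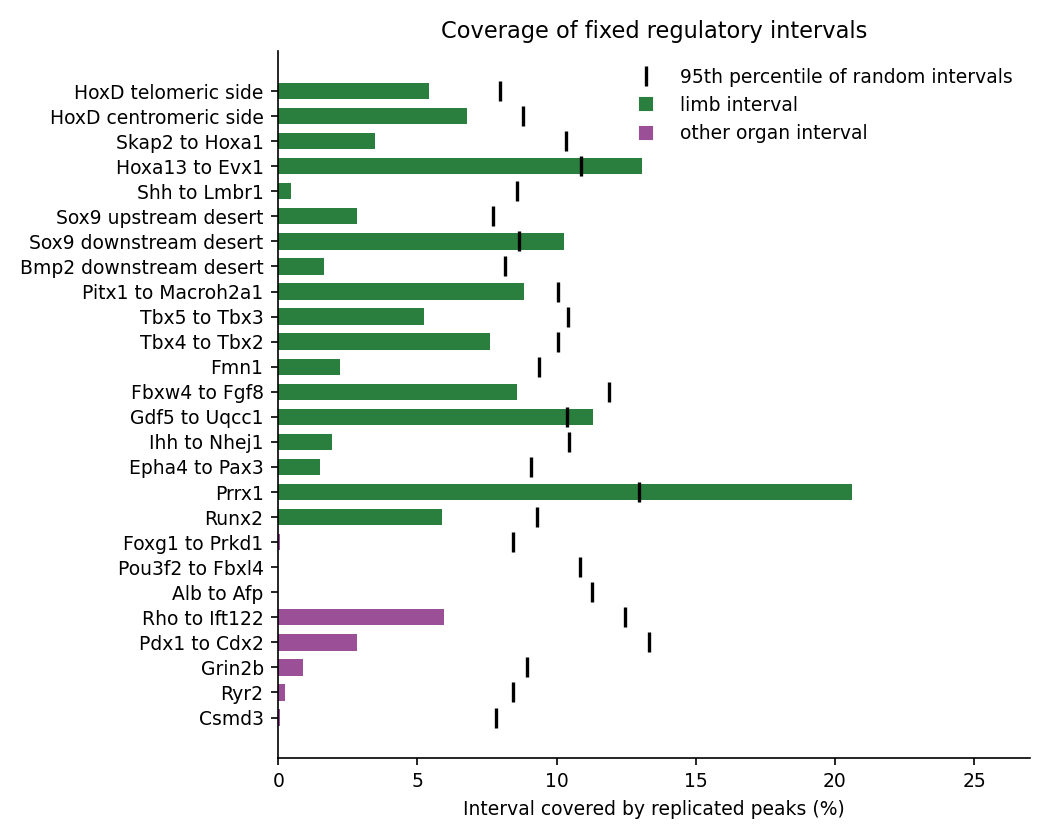
Share of each fixed interval covered by replicated peaks (x axis, percent) for 18 limb intervals (green) and 8 intervals of other organs (purple). Black ticks give the 95th percentile of 1000 random intervals of the same length, which Hoxa13 to Evx1, the Sox9 downstream desert, the Gdf5 to Uqcc1 span and Prrx1 passed.

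The strongest replicated peak, with an enrichment value of 10.02 and a −log10 p of 40.6, lay between genes on chromosome 9 from 35359821 to 35364617, at −60.2 kb from the TSS of Cdon, which encodes a Hedgehog co-receptor (negative distances are upstream). A pair of peaks in introns of Sept9, a septin gene, followed (chromosome 11, 117343581 to 117346489, value 9.81, and 117316398 to 117321161, value 9.15), the first of them nearest to the TSS of Gm11733. Others among the 10 strongest lay at −3.78 kb from the TSS of Sema3f (9.15), at −11.4 kb from that of Dusp7 (9.03), and in introns of Actn1 (8.96), 2010111I01Rik (8.91), Adgra2 (8.79), Nfia (8.51, nearest to the TSS of E130114P18Rik) and Notch1 (8.42). The widest peak covered 14308 bp in an intron of Nfix, a nuclear factor I gene (chromosome 8, 84777275 to 84791582), and a peak of 8808 bp lay in another part of the same gene. Introns of Bcl9l (11264 bp), Smad7 (8949 bp), Igsf3 (8573 bp), Zfp423 (8552 bp), Ahdc1 (8532 bp), Sulf2 (8155 bp) and Rara (7807 bp) held others, and a peak of 8154 bp lay in an intron shared by Coro7 and Dnaja3. All 2472 pooled peaks of at least 2 kb were in the replicated list.

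By covered length within 50 kb of the TSS, the first of all genes was G430095P16Rik with 54.7 kb, which lies within the span of Nfix (40.1 kb), as does Lyl1 (48.7 kb), with Nacc1 (37.5 kb) and Trmt1 (36.4 kb) beside it. Mrpl23 (51.8 kb) and Tnnt3 (45.3 kb) are neighbours on chromosome 7. The transcriptional regulator genes Ski (46.5 kb; 39.2 ± 4.00 kb in the replicates), Gse1 (42.2 kb), Ncor2 (42.1 kb), Rara (40.02 kb), Bahcc1 (39.7 kb), Ahdc1 (37.8 kb) and Zmiz1 (37.3 kb) were among the first 20. So were Synpo (40.7 kb), Smad7, an inhibitor of TGF-β and BMP signalling (38.9 kb), Notch2 (38.6 kb), Dusp7 (37.7 kb), Igsf3 (36.4 kb) and Nxn (36.3 kb). Of all genes, 4971 (22.7%) had no replicated peak within 50 kb.

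Replicated peaks were enriched near genes. Within 1 kb of a TSS lay 9.26% of the summits, 5.54 times the 1.67% of randomly placed peaks, and 20.8% lay 1 to 10 kb from a TSS against 12.9%. Introns further away held 37.9% against 31.3%, exons 2.10% against 2.22%, and regions between genes 29.9% against 51.8%. In the replicates, 7.87 ± 0.948% of summits lay within 1 kb of a TSS and 30.6 ± 3.77% between genes (SD, n = 2), so both differed from the random placements by more than this spread. The median distance to the nearest TSS was 36.6 kb, against 70.5 kb for random placements.

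Around CpG-rich promoters, summits were denser at the flanks than at the start site itself. At 10065 CpG-rich promoters, the density of summits within 250 bp of the TSS was 0.205 of that 500 to 1500 bp away, and at 11846 CpG-poor promoters it was 1.53 times that of the flanks. The ratios in the replicates were 0.231 ± 0.0468 and 1.44 ± 0.0466 (SD, n = 2), so the promoter classes differed by far more than the replicates. A peak lay within 1 kb of the TSS at 70.4% of CpG-rich and 26.3% of CpG-poor promoters.

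**Figure D3:**
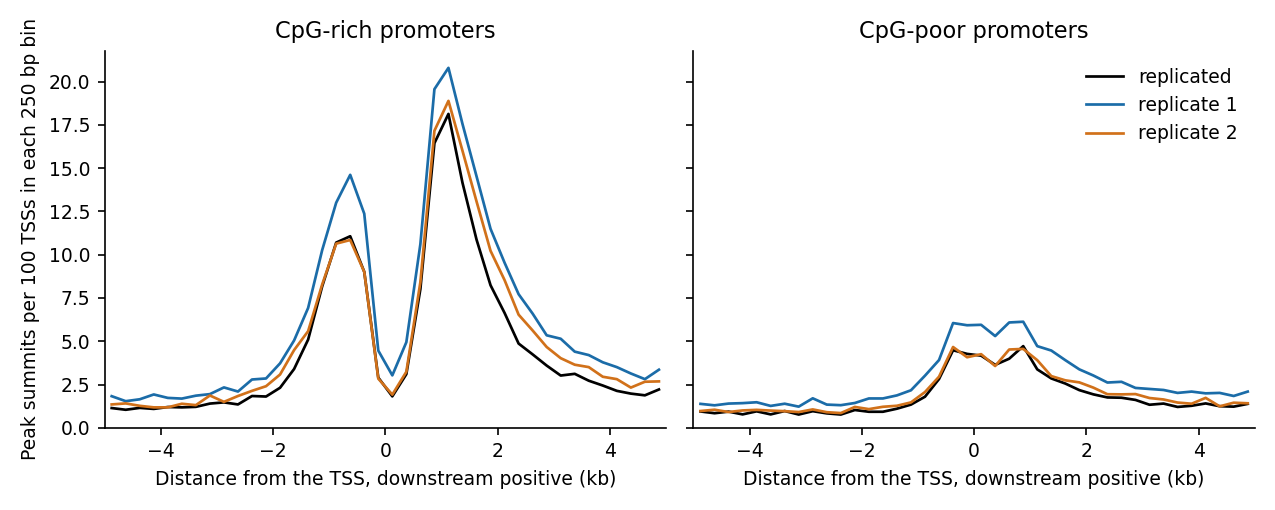
Number of peak summits per 100 TSSs in bins of 250 bp (y axis) by distance from the TSS (x axis, kb) at CpG-rich (left) and CpG-poor (right) promoters, for replicated peaks and the peaks of each replicate. At CpG-rich promoters the density at the TSS is 0.205 of that at the flanks in replicated peaks, and at CpG-poor promoters it is 1.53 times the flanks.

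Of the peaks of replicate 1, 37.3% were shared with replicate 2, and of the peaks of replicate 2, 65.9% were shared with replicate 1. Random placements gave 2.20% and 3.57%. In the strongest 10% of each list, 85.6% and 93.9% of the peaks were shared, and in the weakest 10% 14.7% and 48.4%. The median width of peaks fell as well, from 736 to 224 bp in replicate 1 and from 597 to 202 bp in replicate 2. Random placements were made for whole lists only, so the share expected in each class is unknown. Across 62190 overlapping pairs of peaks, the log2 enrichment values had a Spearman's rho of 0.284 and a Pearson's r of 0.317, and the median ratio of replicate 1 to replicate 2 was 0.991. Covered length around genes had a rho of 0.951 between the replicates across all genes, with a median of 2.503 kb in replicate 1 and 1.285 kb in replicate 2. This is another measure over another set, which includes genes without a peak, so it cannot be set against the correlation of peak values. Peaks and genes are not independent replicates, so these correlations carry no p. Requiring 50% of both peaks lowered the shared share of replicate 2 to 33.1% and that of replicate 1 to 20.9%.

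**Figure D4:**
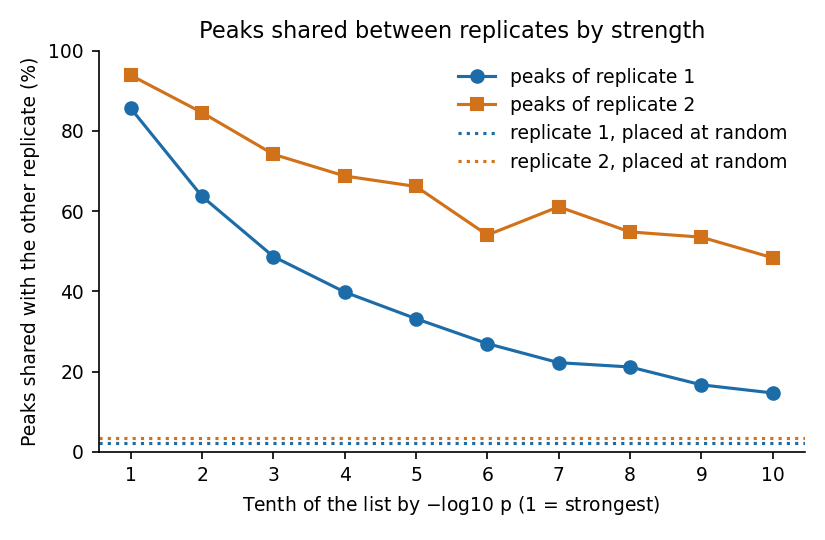
Share of peaks shared with the other replicate (y axis, percent) by class of strength in each replicate's list (x axis, 10 classes of equal size, 1 is the strongest by −log10 p). Dotted lines give the mean of 100 random placements of the whole list, 2.20% for replicate 1 and 3.57% for replicate 2. The shares fall from 85.6% to 14.7% for replicate 1 and from 93.9% to 48.4% for replicate 2.

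The authors' replicated list kept 65.5% of the pooled peaks, 99.9% of the strongest 10% and 18.4% of the weakest 10%. Part of the replicated peaks had no peak in the list of 1 or both replicates. Of the 99452 replicated peaks, 63845 (64.2%) overlapped a peak in both replicate lists by 50% of the shorter, 25932 only in replicate 1, 6882 only in replicate 2 and 2793 in neither. An overlap of 1 bp in both was found for 64736 (65.1%) and not for 34716. No pooled peak with the 50% overlap in both was left out. A replicated list rebuilt by this overlap held 42.0% of the pooled peaks.

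Chromosome X had 464 replicated peaks, which covered 0.117% of it, against 2.62% of the autosomes, a ratio of 0.0445. The ratio was 0.0756 for replicate 1 and 0.0420 for replicate 2, 0.0588 ± 0.0237 (SD, n = 2). Chromosome X held 5.80 protein-coding genes per Mb, against 8.67 on the autosomes. Among the autosomes, the covered share ran from 2.01% of chromosome 3 to 3.91% of chromosome 11. Chromosome Y had no replicated peak.

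**Figure D5:**
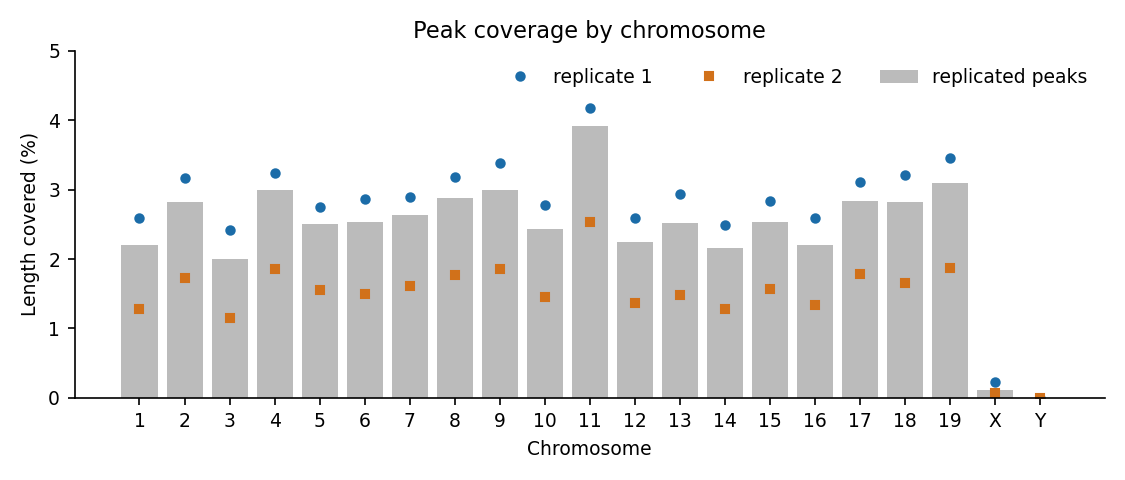
Share of each chromosome covered by replicated peaks (grey bars) and by the peaks of each replicate (points), in percent. Chromosome X, with 0.117%, lies far below every autosome, the lowest of which is chromosome 3 with 2.01%.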

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

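Chosen only after the data were seen were the overlap in both replicates' own lists, the lists without genes on chromosome X or with 1 member of each group of overlapping windows, the 50000 strongest peaks of each replicate for gene lists, and the replicated list rebuilt with 1 bp; the others were planned. The number of limb lists at or above the 95th percentile, 4, was between 4 and 6 under every alternative, and the number of intervals of other organs stayed at 0. The share of replicate 1 and of replicate 2 peaks that were shared was 43.2% and 75.1% with an overlap of 1 bp, 20.9% and 33.1% with 50% of both peaks, 46.0% and 52.0% with the 50000 strongest peaks of each, and 26.9% and 73.5% with a q of 0.01 or lower, where the lists differ most in length. The correlation of values was 0.234 in the 50000 strongest and 0.327 with −log10 p. The share of pooled peaks kept was 42.0% when rebuilt with 50% overlap, 43.2% with 1 bp and 90.7% in the stronger 50%. Peaks within 1 kb of a TSS were 7.20% to 8.54% with a replicate left out, and 18.5% lay within 2.5 kb. Over all promoters together, the ratio at the TSS was 0.498 in the main result, 0.399 in the stronger 50% of peaks and 0.470 to 0.568 with a replicate left out. In replicates 1 and 2 it was 0.264 and 0.198 at CpG-rich promoters, and 1.47 and 1.40 at CpG-poor ones. Of the lists of other organs, 1 reached the 95th percentile without replicate 1, without replicate 2, with the number of peaks, with the overlap in both replicates' own lists, with 1 member of each group of overlapping windows and with the 50000 strongest peaks of replicate 2, against 0 in the main result. With the stronger 50% of peaks, 2 limb intervals reached it. The ratio of chromosome X to the autosomes was 0.0420 to 0.0756 with a replicate left out. Where no cause is named, the cause was not tested. Among the percentiles of single lists and intervals, 177 of 464 values under alternatives moved by more than the SD between the replicates. Among the summary results, such as the replicate overlap and correlation, 25 of 69 values moved by more than the limit set for each, and none is a test. The lists hold no read counts, so peaks missing in a replicate cannot be called absent. Windows without a replicated peak can still hold a peak in the list of a replicate, as that of Fgf10 does. No paired analysis was possible because there is 1 group.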

Other observations

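The gene families and X-linked genes described here, the test of −log10 p between replicates and the test of chromosome X by strength of the peaks were chosen, and the test on X-linked genes was narrowed to the number of genes, only after the results were seen. Families of at least 15 genes with a shared symbol stem, without genes on chromosome X, were compared with matched random lists in the same way as the fixed lists, 143 families in all. Of these, 36 reached the 95th percentile and 36 lay at or below the 5th. The stems Tmem (235 genes), Ppp (74 genes) and Ccdc (136 genes), not chosen for a role in the limb, lay at percentiles 100, 99.88 and 99.75. A percentile that high is therefore not particular to lists of limb genes. The medians of these stems were 3.57, 4.30 and 3.50 kb, against 2.32, 2.47 and 2.41 kb in matched random lists. The limb patterning factors had 9.85 kb against 1.75 kb. Medians of longer random lists vary less, and these stems hold more genes than any limb list, so equal percentiles do not mean equal rises. Wnt genes, which encode secreted growth factors, had a median of 6.49 kb within 50 kb of the TSS (4.91 ± 1.89 kb in the replicates, SD, n = 2), and all 19 had a peak. The stems Hist (histones), Bcl and Tspan (tetraspanins) had 6.43 kb (5.06 ± 2.15 kb), 6.42 kb (5.55 ± 1.36 kb) and 6.24 kb (5.09 ± 1.28 kb). The differences between these 4 families were smaller than this SD, which ignores that each replicate gave all of them. In replicates 1 and 2, Bcl (6.51 and 4.59 kb) lay above Wnt (6.25 and 3.57 kb) and Tspan (6.00 and 4.185 kb). Hist lay above Bcl in replicate 1 (6.58 kb) and below it in replicate 2 (3.55 kb). The 67 Hist genes lie in 7 groups of overlapping windows, so their median describes a few loci. Wnt11 had 26.0 kb, Wnt5a 13.4 kb and Wnt9a 12.9 kb. The 43 genes with the stem Col, mostly collagens, had a median of 5.18 kb, with 28.8 kb at Col5a1, 18.8 kb at Col4a1 and 13.4 kb at Col2a1, and all of them had a peak. Semaphorin genes had 5.63 kb, and the stems Unc and Abhd 5.53 and 5.28 kb. Genes with the stems Rps and Rpl, mostly ribosomal protein genes, had 4.24 and 3.92 kb.

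At the other end, 58 of 100 cytochrome P450 genes (Cyp), 44 of 57 hair keratin-associated protein genes (Krtap), 25 of 25 prolactin family genes (Prl) and 18 of 19 carboxylesterase genes (Ces) had no replicated peak within 50 kb, and each family had a median of 0 kb. Members of the Krtap, Prl and Ces families lie side by side, in 9, 6 and 3 groups of overlapping windows. Of 22 beta protocadherin genes, 21 had none, but they share 1 group of overlapping windows. The 385 zinc finger genes with the stem Zfp had a median of 1.88 kb, against 2.57 kb for matched random lists. Of the 948 genes on chromosome X, 738 (77.8%) had no replicated peak within 50 kb, against 19.5% of autosomal genes. Those with the most were Gpc3, a glypican gene mutated in an overgrowth syndrome, with 7.29 kb, the group around Bgn, the biglycan gene, with 6.94 kb, and Bcor with 6.88 kb.

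Few peaks lay on chromosome X. The number of genes does not account for the whole of this, since X-linked genes matched to autosomal genes on length and neighbours had 0.0616 of their covered length (central 95% of draws 0.0568 to 0.0671). The share of bases outside masked repeats was 0.800 of that on the autosomes. Masking does not measure where reads can be aligned, so this value cannot decide whether reads that cannot be placed play a part. Fewer regulatory sites around each X-linked gene would give the same low coverage and were not tested. A lower signal on X against a calling threshold set on all chromosomes stays open: the ratio of X to autosomal peaks per Mb was 0.00869 in the strongest 10% of the pooled peaks (95% counting interval 0.00452 to 0.0167) and 0.0884 in the weakest 10%, although it was highest, 0.187, in class 8 of 10 by strength. No biological explanation was tested.

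Replicate 1 had 1.58 times as many peaks as replicate 2. The median GC content at summits of peaks of replicate 1 alone was −0.800 percentage points relative to those of replicate 2 alone (95% bootstrap interval −1.20 to −0.800). This lay within the limit of 2 points set beforehand, which argues against a larger difference between these sets. A smaller GC bias stays open. The interval excludes 0, but it was made by resampling peaks within 1 library each, so it does not measure the spread between libraries. Peaks of replicate 1 alone had a median of 46.4%, against 48.4% for its shared peaks, and those of replicate 2 alone 47.2% against 48.4%. Lower read depth behind replicate 2 is a candidate explanation: at matched enrichment values, the −log10 p of shared peaks in replicate 2 was 0.756 ± 0.0579 of that in replicate 1 (median and SD over 20 bins of value). A different mix of cell types cannot be told apart. With equal numbers of peaks, 0 of 11 lists of limb genes and limb cell types, or 0.0%, had a ratio of covered length outside the central 95% of random lists. A count of 11 allows up to 25.9% (Wilson, 95%), and the lists of patterning factors and of signalling genes among them mark no single cell type. The controls also differed between the replicates, 2 files against 1, which was not tested, nor was any biological difference between the pools of embryos.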
